A study of Trachinotus carolinus with 19 samples.

How the data were processed

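The samples were 19 juvenile Florida pompano in 7 groups of 2 or 3 fish, grouped by sampling day and tank set as the sample titles give them. Per the labels' protocols, fish of about 5 g were moved to 300 L recirculating tanks at 28 ppt, and salinity fell by 5, 4 or 2 ppt per day over 4 days to reach 8, 12 or 20 ppt. Control tanks had matching water changes. Liver, anterior intestine and gill of 1 fish were combined, and poly-A libraries were sequenced on an Illumina NovaSeq. The labels mention 21 libraries, of which 19 were used here. Per the labels, each salinity had 3 tanks and 1 fish per tank and day was taken for RNA, so replicates are separate fish.

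The deposited values of both tables are on a log2 scale and come from a variance-stabilising transformation of normalised read counts, made by the authors. The submitters' processing notes name DESeq2, without a version. The aligner, the counting tool, the reference and the annotation are not given in the sources used here, so reads shared between related genes could not be assessed. Genes and transcripts with a count of 0 share 1 lowest value, 3.86 in the gene table and 5.20 in the transcript table, which compresses differences between low genes: a log2 difference understates the change of a gene near that value. Each table gives 1 column per fish, named by day, salinity and letter. The files do not pair identifiers with gene names and no reference was given for this organism, so of the 27 gene lists fixed before the data were examined, 0 could be matched, and the gene list tests and tissue marker scores were not run. For the same reason at most 2 identifiers that rose and 2 that fell are named: the largest change in each direction in the comparison of 8 with 28 ppt and in the average change over time, among genes past the threshold whose groups did not overlap.

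Depth was read from the transcript table. Transformed counts of 1 library fall on discrete steps, so ranking the steps gives the whole number of reads behind each value. Between 99.90% and 99.99% of the detected transcripts of a library lay on such a step, within 0.15 of a whole number, and 2 to 17 transcripts per library, all abundant, lay above the last resolved step. On 3 simulated libraries at least 99.98% of counts came back equal and library totals were within 0.123%. Recovered totals were 8255387 to 14940793 reads per library. The gene table does not lie on whole-read steps, so its depth is not known and the planned voom fit on gene counts was not run. Limma voom was run on the recovered transcript reads in its place, a choice made after seeing the data.

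Differences were tested with limma 3.58.1 in R 4.3.3, a linear model with moderated variances and a mean-variance trend, on the deposited gene values. All 19 fish entered 1 model with a mean for each of the 7 groups. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. A gene was tested if its value lay more than 1 above the lowest value of the table in at least 2 fish, which kept 18213 of 19980 genes. The slope over salinity used the 11 day 14 fish. The share of variance between groups used Euclidean distances and every arrangement of the fish among the groups; 100000 random arrangements gave p = 0.216 for salinity on day 14, as the exact count did. Overlaps of comparisons that share day 0 fish were set against 100 simulations of unchanged groups.

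The limma step was tested on simulated values for the 18213 genes, with 200 genes changed. Each gene had its mean over the groups and 1 residual spread shared by all groups. For 8 against 28 ppt it found 2% of the genes changed 2-fold, 48% of those changed 4-fold, 84% at 8-fold and 96% at 16-fold, and called 9 unchanged genes. For the average change from day 0 to day 14 it found 32%, 88%, 100% and 100%, and called 7 unchanged genes. The median 95% interval reached 1.06 (log2) to either side of a difference between 8 or 20 and 28 ppt, 1.19 for 12 ppt and 0.66 for the average change over time.

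Alternatives fixed before the data were examined covered the filter on low values, scaling, trend, robust and weighted fits, an adjusted p of 0.10, the fish in the model, the replicate letter as a block, the form of the slope, the distance measure, the transcript table and leaving out each fish. After the data were seen, the voom fit and a fit without the 3 fish that stand apart on the first principal component were added. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the recovery of reads, and matplotlib 3.10.9 for the plots.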

Results

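RNA was measured in juvenile Florida pompano (*Trachinotus carolinus*), a marine fish raised in aquaculture, to learn how lowered salinity affects the health of the fish. Each library came from 1 fish, with liver, anterior intestine and gill combined before RNA extraction, so a value is an average over 3 tissues whose shares in the pool were not measured. The sample records and the dissection notes name these tissues, but the extraction notes name immune organs in place of the intestine. Fish were stocked at 25 per 300 L tank, with 3 tanks per salinity. Salinity was lowered from 28 ppt over 4 days to 20 ppt (estuarine), 12 ppt (isosmotic) or 8 ppt (hypoosmotic), and the remaining tanks stayed at 28 ppt as the marine control. Fish were taken on day 0, before any change, and on day 14. On day 0, 3 fish came from the 8 ppt tanks, 2 from the 12 ppt tanks and 3 from the 20 ppt tanks, all still in 28 ppt water, so that a salinity named for day 0 names the tank set. On day 14 there were 3 fish at 8 ppt, 2 at 12 ppt, 3 at 20 ppt and 3 at 28 ppt. Day 0 fish of the 28 ppt tanks were not analysed here.

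The deposited tables hold variance-stabilised values on a log2 scale for 19980 genes and 27888 transcripts. They name genes only by a numeric identifier, do not pair these with gene names, and no table of names was at hand. Ion transport, immune, fatty acid and tissue marker genes could therefore not be picked out, and none of the 27 gene lists fixed for this tissue and treatment was tested. Whole reads recovered from the steps of the transcript values came to between 8255387 and 14940793 per library. The 3 fish of 8 ppt on day 14 had 84.5% ± 1.39 (SD, n = 3) of the genes above the lowest value in the table, against 73.3% ± 2.07 (SD, n = 3) at 20 ppt and 73.4% ± 7.10 (SD, n = 3) at 28 ppt. The depth of these groups was 11387438 ± 761522, 10803650 ± 963073 and 13329721 ± 2245501 reads (SD, n = 3 each).

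Fish of one group correlated across genes with Pearson's r between 0.856 and 0.942, and no 2 libraries were copies of one another. The first principal component, with 23.8% of the variance, set apart 20 ppt fish c and 28 ppt fish a and c of day 14, at scores of 109, 93.3 and 77.7 against a highest score of 35.2 among the other 16 fish. The second component, with 13.2%, held the 8 day 0 fish at scores between 21.3 and 51.9, above each of the 11 day 14 fish, whose highest score was 19.6. Salinity accounted for 34.7% of the variance among the 11 day 14 fish, not more than chance arrangements of the fish gave (median 29.1%, exact permutation p = 0.216, 92400 arrangements). Day accounted for 15.3% of the variance in the 8, 12 and 20 ppt tanks (exact permutation p = 1.554e-04, the smallest that 12870 arrangements can give), where chance arrangements had a median of 6.28%.

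**Figure D1:**
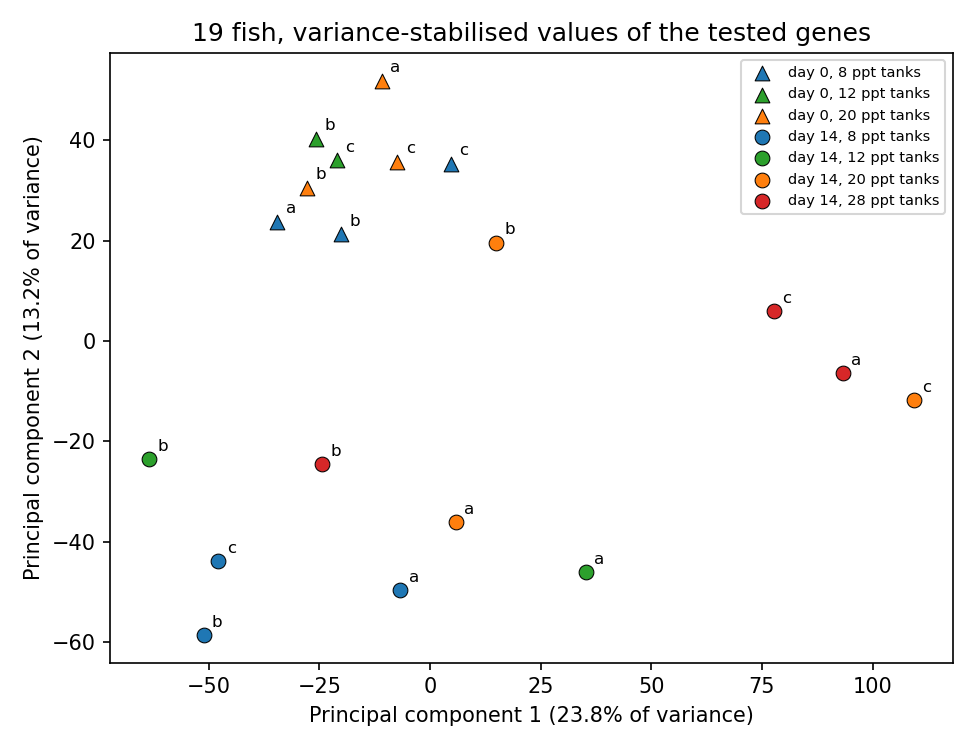
Scores of the 19 fish on the first 2 principal components of the tested genes, which hold 23.8% and 13.2% of the variance. Triangles are day 0 fish, circles day 14 fish, colours the tank sets and letters the replicates; 20 ppt fish c and 28 ppt fish a and c of day 14 lie at the right, with scores of 109, 93.3 and 77.7.

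The comparison of hypoosmotic with control water asked what the widest salinity step did after 14 days. Of 18213 genes tested, 8 differed between 8 and 28 ppt: 7 were higher at 8 ppt and 1 was lower (limma, Benjamini-Hochberg adjusted p under 0.05). Gene 111236045 rose most, by 4.35 ± 0.597 on the log2 scale (SE; adjusted p = 0.00121 in limma), a 20.4-fold difference. Its mean was 9.83 ± 0.757 (SD, n = 3) at 8 ppt, 8.04 ± 1.31 (SD, n = 2) at 12 ppt, 6.64 ± 1.07 (SD, n = 3) at 20 ppt and 5.48 ± 0.388 (SD, n = 3) at 28 ppt. On day 0 it lay between 4.92 and 5.48 in the means of the 3 tank sets. Gene 111217996 was the 1 lower at 8 ppt, by 2.71 ± 0.517 (SE, adjusted p = 0.0467 in limma). Its mean was 9.54 ± 0.681 (SD, n = 3) at 28 ppt and 6.83 ± 0.248 (SD, n = 3) at 8 ppt, with 7.41 at 12 ppt and 8.57 at 20 ppt in between. Its day 0 means lay between 7.81 and 8.04, so part of the gap was a rise of 1.61 at 28 ppt against day 0. Signed by their direction at 8 against 28 ppt, the 8 genes changed from day 0 by a median of 2.59 in the 8 ppt tanks and -0.411 at 28 ppt. The genes were chosen for the gap between these same 8 and 28 ppt fish, which tends to push the 2 medians apart. In each of the 8 genes the 4 day 14 means followed the order of the salinities, and the 3 fish at 8 ppt did not overlap the 3 at 28 ppt. Such separation occurred in 16.9% of all genes, where chance gives 10% for 3 against 3. The 7 higher genes had means between 7.69 and 9.83 at 8 ppt and between 4.32 and 6.21 at 28 ppt, and over the 8 genes 5 values at 28 ppt were at the lowest value in the table.

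Beyond the 8 genes, 2838 genes (15.6%) had an unadjusted p under 0.05 between 8 and 28 ppt, and 70.6% of these were higher at 8 ppt. That share depends on scaling: the median gene was 0.21 higher at 8 ppt (log2), and with each fish centred on its median 48.6% of 2599 genes were higher. After centring, gene 111236045 was 4.15 higher and gene 111217996 2.91 lower at 8 ppt, both still past the threshold. Over the alternatives in which each was tested, the call of the former was lost in 4 of 30 and that of the latter in 16 of 31. The stricter filter on low values removed the former, so it could not be called there. The count of 8 rested on single fish. It was 907 without 28 ppt fish b, 3 without 28 ppt fish a, 2 without 8 ppt fish b, 14 without 20 ppt fish a and 13 without 20 ppt fish c. Without 20 ppt fish c and 28 ppt fish a and c, which stand apart on the first component, 1 fish is left at 28 ppt and its spread is taken from the other groups. No gene passed (0), with gene 111236045 at 4.17 ± 0.850 and gene 111217996 at -2.43 ± 0.646 (SE). These 2 calls ended with larger errors on similar differences. The count was 13 without the filter on low values, 17 with a robust fit and 113 with sample weights. It was 0 with a stricter filter, which kept genes whose mean lay more than 3 above the lowest value. That filter removed most of the 8 genes, so they could not be called there, while gene 111217996 was tested and missed the threshold. The count was also 0 when the day 14 fish alone, or the 6 compared fish alone, entered the model. The transcript table gave 22 transcripts by the same limma fit and 446 by limma voom on the recovered reads.

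**Figure D2:**
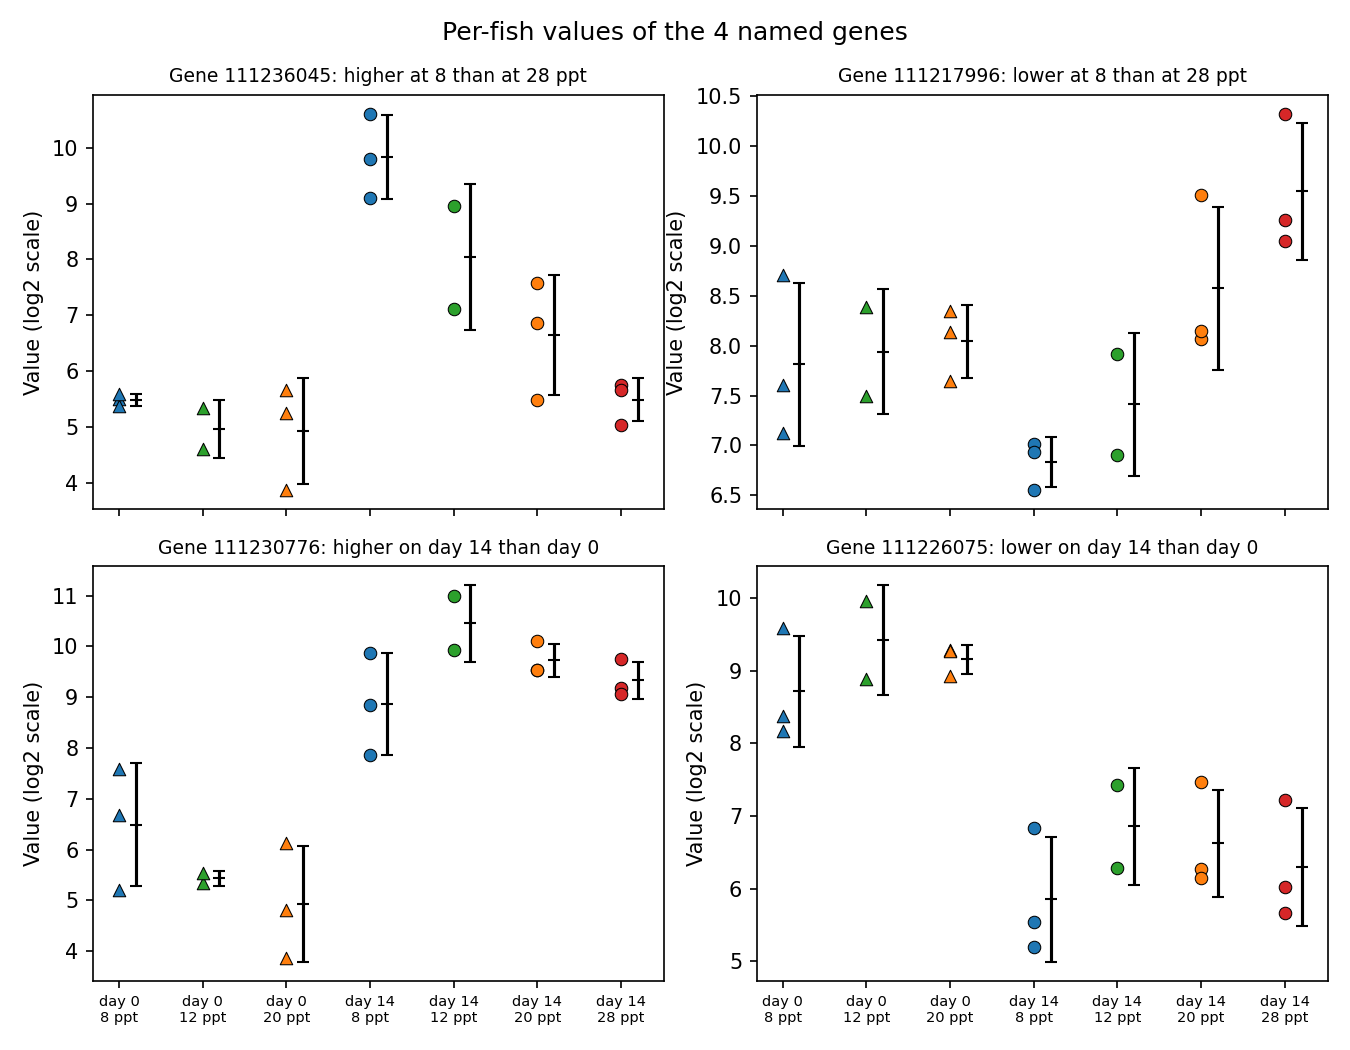
Values of the 4 named genes in each fish, on the log2 scale of the deposited table, by sampling day and tank set. Each point is 1 fish; the bar beside the points is the group mean with its SD (n = 2 at 12 ppt, n = 3 elsewhere). Gene 111236045 had means of 9.83, 8.04, 6.64 and 5.48 at 8, 12, 20 and 28 ppt on day 14.

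Neither 12 nor 20 ppt differed from 28 ppt in any gene by limma on the gene table. Gene 111236045 was 2.55 ± 0.667 (SE) higher at 12 ppt than at 28 ppt and 1.16 ± 0.597 (SE) higher at 20 ppt, both short of the threshold over all genes (adjusted p = 0.671 and 0.842 in limma). At unadjusted p under 0.05 there were 1339 genes (7.35%) for 12 ppt and 1085 (5.96%) for 20 ppt. Among transcripts, limma gave 10 and 3, and limma voom on the recovered reads 200 and 45. The 95% intervals excluded a difference of 2 (log2) in 72.3% of genes for 12 ppt and 86.1% for 20 ppt, but of 1 in only 2.91% and 6.23%. Near the lowest value, where differences are compressed, this does not exclude a 4-fold change in reads. The model shares 1 spread over the 7 groups, and fish at 12, 20 and 28 ppt on day 14 varied more than the rest, so these intervals may be too narrow. In simulated data of the same design, 36% of genes changed by 2 (log2) were found for 12 ppt and 52% for 20 ppt. The simulation also shared 1 spread per gene over the groups, so these shares may be too high. Without 28 ppt fish b, 4 genes passed for 12 ppt.

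Among the lowered salinities, 0 genes passed for 8 against 20 ppt (limma; 3044 at unadjusted p under 0.05, smallest adjusted p 0.0586), 0 for 8 against 12 ppt (472) and 0 for 12 against 20 ppt (1257). The same limma fit on the transcript table called 19, 9 and 4 transcripts, and limma voom 450, 227 and 194. The count for 8 against 20 ppt rose to 244 without 20 ppt fish a, 27 without 28 ppt fish b, 15 without 28 ppt fish c and 3 without day 0 8 ppt fish b. It was 1 without the trend, 3 with a robust fit, 8 with sample weights and 4 without the 3 fish that stand apart. With only the compared fish in the model, 12 against 20 ppt gave 91 genes, from 5 fish. A linear slope over the 4 salinities gave 0 genes (limma; 2886 at unadjusted p under 0.05), 0 transcripts by limma and 229 by limma voom; 297 genes passed without 28 ppt fish b, 11 with a robust fit, 3 with sample weights, 1 without the trend, 1 with median centring and 4 over log2 of ppt. The median gene had a slope of -0.10 per 10 ppt. An F test for any difference among the 4 salinities gave 4 genes (limma), all 4 also among the 8 of 8 against 28 ppt. That count was 0 without 8 ppt fish a or b, 2 without 28 ppt fish a, 1 without 28 ppt fish c, 27 without 20 ppt fish a and 141 without 28 ppt fish b. It was 11 without the filter on low values and 11 with sample weights. A stricter filter gave 0, but it removed the 4 genes of the main fit, so they could not be called there. With only day 14 fish in the model the count was 0. The transcript table gave 31 by limma and 562 by limma voom.

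The 3 tank sets on day 0, all in 28 ppt water, served as a baseline for fish that differed in tank alone. They differed in 0 genes (limma F test; 472 at unadjusted p under 0.05), and tank set accounted for 27.7% of the variance, where chance arrangements had a median of 28.3% (exact permutation p = 0.646, 560 arrangements). The same fit on transcripts gave 3. Limma voom on the recovered reads gave 99 transcripts in this comparison without a difference in water.

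Day 14 against day 0 in the 8, 12 and 20 ppt tanks showed what changed over the trial, with salinity, age and sampling day changing together. On average over the 3 tank sets 309 genes rose and 218 fell (limma, adjusted p under 0.05), 507 of these 527 by more than 2-fold. Gene 111230776 rose by 4.06 ± 0.379 on the log2 scale (SE, adjusted p = 1.161e-06 in limma). It went from 6.49 ± 1.21 to 8.86 ± 1.01 in the 8 ppt tanks (SD, n = 3 on each day), from 5.44 ± 0.145 to 10.45 ± 0.752 in the 12 ppt tanks (SD, n = 2) and from 4.93 ± 1.14 to 9.73 ± 0.323 in the 20 ppt tanks (SD, n = 3). Gene 111226075 fell by 2.65 ± 0.349 (SE, adjusted p = 1.357e-04 in limma), and its means were 5.85, 6.86 and 6.63 on day 14 at 8, 12 and 20 ppt, against 8.71, 9.42 and 9.16 on day 0. In each of these genes the 8 day 14 fish and the 8 day 0 fish did not overlap, as in 32 of the risen and 44 of the fallen genes, where chance gives 0.0155% of genes and 0.489% of all genes were seen. The 4553 genes with the highest mean values held 147 of the risen and 131 of the fallen genes. The direction was shared by the 3 tank sets for 511 genes, which were chosen on the average of those sets.

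The split into 309 risen and 218 fallen genes depended on scaling: it was 235 and 286 with each fish centred on its median, 328 and 328 after quantile normalization, and 240 and 240 with a stricter filter on low values. The count of 527 fell to 128 without 12 ppt fish a of day 14, 221 without 8 ppt fish b and 320 without 8 ppt fish a of day 14, and it was 801 without 12 ppt fish b of day 14. Of day 0 fish, leaving out 12 ppt b gave 189, 12 ppt c 217, 20 ppt a 282, 8 ppt a 286 and 20 ppt b 329. The lowest count, 2, came with tank set and letter as a factor in the model, while as a random effect they gave 547. In the factor fit gene 111226075 fell by 2.28 and lost its call (adjusted p = 0.1007 in limma). Gene 111230776 rose by 3.92 there and kept its call (adjusted p = 0.00798 in limma). The factor fit held only the fish of the 7 tank set and letter pairs with a fish on both days, a single pair of them at 12 ppt. The random effect fit held all 19 fish, so the fall to 2 came with fewer fish as well as with the pairing. The letters did not pair the fish by the rule given further below. The transcript table gave 198 by limma and 378 by limma voom.

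Within single tank sets 13 genes rose and 2 fell at 8 ppt, 2 rose at 12 ppt, and 25 rose and 7 fell at 20 ppt (limma). With only the 2 compared groups in the model no gene passed in any of the 3 (0, 0 and 0; smallest adjusted p 0.0563, 0.224 and 0.119). With sample weights 646 passed at 8 ppt and 21 at 20 ppt; quantile normalization gave 37 and a robust fit 29 at 8 ppt, a robust fit or no trend 4 at 12 ppt, and a stricter filter 20 at 20 ppt. The transcript table gave 35, 7 and 12 at 8, 12 and 20 ppt by limma and 422, 195 and 42 by limma voom, and without the 3 fish that stand apart 85 genes passed at 8 ppt. The change did not differ between the tank sets in any gene by the test of that difference (limma F test, 0 genes; 932 at unadjusted p under 0.05; 0 transcripts by limma and 58 by limma voom; 1 gene without 20 ppt fish a of day 14). The 32 genes at 20 ppt became 1 without 20 ppt fish c of day 14, the fish farthest out on the first component, and 74 without fish b, 50 without fish a, 9 without day 0 fish a and 14 without day 0 fish b of that tank set. They became 65 without either 12 ppt fish of day 14 and 61 without 28 ppt fish b. The 15 genes at 8 ppt became 6, 3 and 5 without fish a, b or c of day 14 and 7, 7 and 2 without fish a, b or c of day 0 in those tanks. They became 31, 32 and 34 without 20 ppt fish a, b or c of day 14, 25 without 28 ppt fish a, 38 without 28 ppt fish b and 9 without day 0 20 ppt fish a. The 2 genes at 12 ppt became 0 without day 14 fish a or either day 0 fish of those tanks, 5 without 20 ppt fish a of day 14, and 4 without day 0 8 ppt fish b or c.

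**Figure D3:**
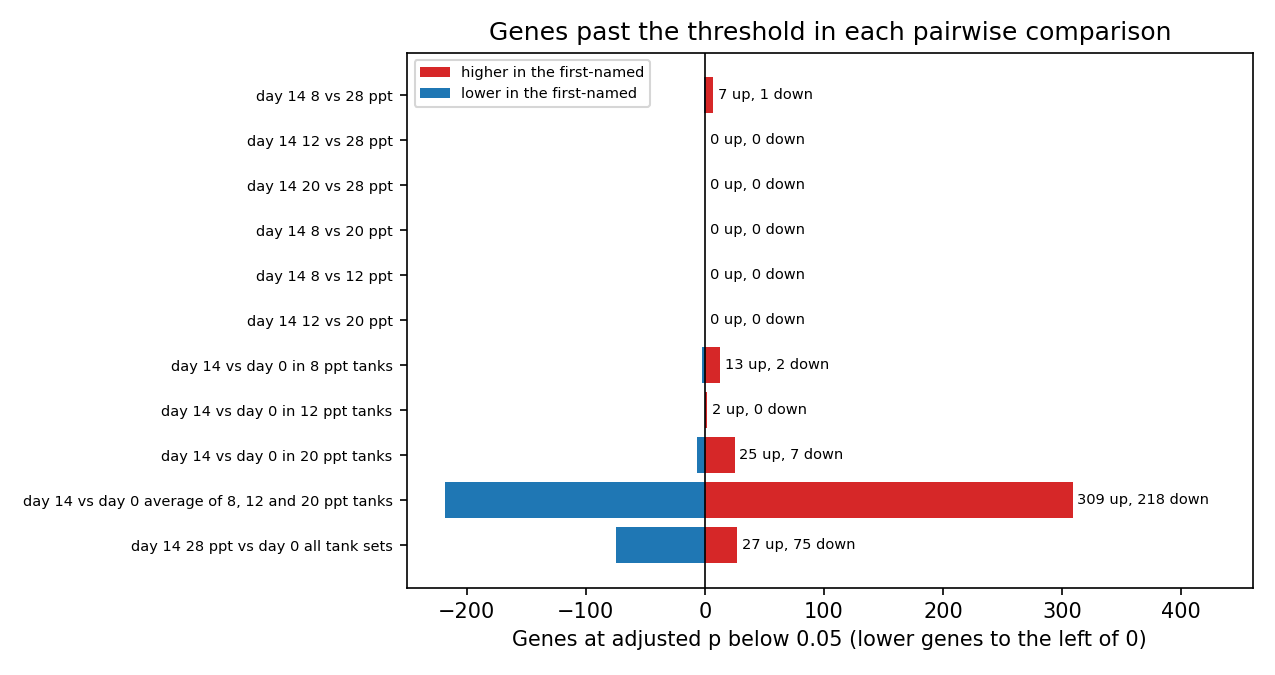
Number of genes at adjusted p under 0.05 (limma) in each pairwise comparison, with genes higher in the first-named group to the right of 0 and lower genes to the left. The average change from day 0 to day 14 has 309 higher and 218 lower genes, and 8 against 28 ppt has 7 and 1.

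The 28 ppt fish of day 14 against the day 0 fish of the other tanks compared fish that were both in 28 ppt water, 14 days apart. Here 27 genes were higher and 75 lower on day 14 (limma). Gene 111230776 was 3.71 ± 0.507 higher (SE, adjusted p = 0.00214 in limma) and gene 111226075 fell by 2.80 ± 0.466 (SE, adjusted p = 0.00775 in limma), in water kept at 28 ppt. Both genes had been chosen for their change against these same day 0 fish, which favours a change of the same sign here. The risen and the fallen gene next in size without overlap on average over time (3.78 and -2.30) changed less here. They differed by 1.87 ± 0.481 and -1.11 ± 0.465 (SE), short of the threshold (adjusted p = 0.0645 and 0.233 in limma). With only the compared groups in the model 0 genes passed (smallest adjusted p 0.0724). The differences of genes 111230776 and 111226075 were the same, with SE of 0.560 and 0.424 and an adjusted p of 0.0785 for each in limma. The count was 173 with a stricter filter on low values and 23 with sample weights, and the transcript table gave 9 by limma and 74 by limma voom. Without 20 ppt fish c and 28 ppt fish a and c, 1 fish is left at 28 ppt, taken to vary like the other groups. Then 0 genes passed, and the 2 genes differed by 4.14 ± 0.808 and -3.08 ± 0.680 (SE; adjusted p = 0.245 and 0.344). The count of 102 was 5 without 28 ppt fish a, 61 without 28 ppt fish c and 936 without 28 ppt fish b. It was 214 without 20 ppt fish c, 173 and 175 without 12 ppt fish a or b of day 14, and for day 0 fish 40 and 51 without 8 ppt a or b, 22 and 27 without 12 ppt b or c, and 59 and 27 without 20 ppt a or b.

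Genes that changed in the lowered tanks were compared with those that changed at 28 ppt. Of the genes called in both, 13 rose in both, 40 fell in both and 0 went opposite ways, where independent lists would share 0.458 and 0.898. Both comparisons use the same day 0 fish, so fold changes correlate with no effect at all: across genes r was 0.578, against 0.373 in simulated unchanged groups, and the covariance was 0.211 against 0.0605. With the day 0 fish split between the comparisons, 4 to each, r was between 0.299 and 0.486 over 36 splits and the covariance had a median of 0.167. Of the 527 genes, 93.0% had the same sign at 28 ppt, against 84.4% of as many genes with the largest changes in simulated unchanged groups that share the day 0 fish. With 527 genes chosen anew in each split, by smallest p and without the fish their sign was then read in, 74.0% to 88.0% had the same sign, where simulated unchanged genes that vary independently gave 45.5% to 54.3%. Most of these genes were not called: a median of 2 per split (0 to 23) were past the threshold, and 26 of 36 splits had any. A direct test of the mean of the lowered salinities against 28 ppt on day 14 gave 0 genes (limma; 1821 at unadjusted p under 0.05).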

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

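Over 506 alternatives of the counts and of the variance share, 363 stayed within 1.5 times of the reported value, 60 were lower and 83 higher. Counts of 0 that stayed at 0 are among the 363, so this total hides how far other counts moved. Leaving out 1 fish moved 8 against 28 ppt further in 5 of 19 refits and 28 ppt against day 0 in 12 of 19. No single gene followed changed direction in 334 alternatives, but these genes were chosen as the largest called differences without overlap. Leaving out a fish or changing the filter could hardly reverse them. Chosen after the data were seen were limma voom on recovered transcript reads and the fit without 20 ppt fish c and 28 ppt fish a and c of day 14. Gene list tests, marker scores as covariates and voom on the gene table were planned but not run, since identifiers have no names and gene values no whole-read steps. For 8 against 28 ppt gene 111236045 lost its call in 4 of 30 alternatives (limma adjusted p from 4.607e-04 to 0.410), gene 111217996 in 16 of 31 (0.0125 to 1), and for the average change over time gene 111226075 in 1 of 31 and gene 111230776 in 0 of 31; for 28 ppt against day 0 both lost it in 2 of 30, with only the compared groups (adjusted p = 0.0785 for each) and without the 3 fish named above (0.344 and 0.245). The stricter filter on low values removed gene 111236045, so the 30 alternatives of that gene leave this one out. Depth limits genes near the lowest value most, and the gene table's own depth is unknown. Where no reason is given the cause was not tested.

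Without the low-value filter 11 genes passed for any salinity and 13 for 8 against 28 ppt. The stricter filter gave 0 and 0, 20 for time at 20 ppt and 173 for 28 ppt against day 0. It removed the 4 genes called for any salinity and most of the 8 called for 8 against 28 ppt, so these could not be called there. Quantile normalization gave 37 for time at 8 ppt, and median centring 1 for the slope. Without the trend, 1 passed for 8 against 20 ppt, 4 for time at 12 ppt and 1 for the slope. The robust fit gave 17 for 8 against 28 ppt, 3 for 8 against 20 ppt, 29 and 4 for time at 8 and 12 ppt and 11 for the slope. Sample weights gave 11 for any salinity, 113 for 8 against 28 ppt, 8 for 8 against 20 ppt, 646 and 21 for time at 8 and 20 ppt, 23 for 28 ppt against day 0 and 3 for the slope. At an adjusted p of 0.10, which loosens the threshold, there were 25 for 8 against 28 ppt, 123 for 8 against 20 ppt, 1034 for average time, 46, 7 and 84 for time at 8, 12 and 20 ppt, 405 for 28 ppt against day 0 and 1 for the slope. The slope over log2 of ppt gave 4.

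With only day 14 fish in the model, any salinity and 8 against 28 ppt gave 0 and 0. With only the compared groups, these and time at 8, 12 and 20 ppt and 28 ppt against day 0 gave 0 each, and 12 against 20 ppt gave 91, from 5 fish. On the transcript table, limma gave 31 for any salinity, 22, 10 and 3 for 8, 12 and 20 against 28 ppt, 19, 9 and 4 for 8 against 20, 8 against 12 and 12 against 20 ppt, 3 for day 0, 198 for average time, 35, 7 and 12 for time at 8, 12 and 20 ppt and 9 for 28 ppt against day 0. Voom gave 562 for any salinity, 446, 200 and 45 against 28 ppt, 450, 227 and 194 among lowered salinities, 99 for day 0, 422 and 195 for time at 8 and 12 ppt, 58 for the interaction and 229 for the slope. Without the 3 fish, with 1 fish left at 28 ppt, any salinity, 8 against 28 ppt and 28 ppt against day 0 gave 0, 8 against 20 ppt 4, and time at 8 and 20 ppt 85 and 1.

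Leaving out 1 fish at a time gave 0 to 141 for any salinity, 2 to 907 for 8 against 28 ppt, 0 to 4 for 12 against 28 ppt, 0 to 244 for 8 against 20 ppt, 0 to 297 for the slope, 128 to 801 for average time, 2 to 38, 0 to 5 and 1 to 74 for time at 8, 12 and 20 ppt, 5 to 936 for 28 ppt against day 0 and 0 to 1 for the interaction. Where 1 fish was left at 12 or 28 ppt, that fish was taken to vary like the other groups, so a lost call there does not show a lost difference. The share of variance between salinities was 33.3% to 43.1%, and 39.7% with a correlation distance, 38.8% with 1000 genes and 35.0% with transcripts.

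Letters do not pair the fish by the rule that each pair correlates above 0.1: deviations of same-letter fish of a tank set on the 2 days correlated above 0.1 in 1 of 7 pairs, and 2 of the day 0 fish were closest to their own letter. On day 14, fish of different salinities correlated above 0.1 in 9 of 15 pairs with the same letter (-0.182 to 0.451), where relabelling within groups gave a median of 6 pairs, and the mean correlation of 0.116 had an exact permutation p of 0.125 over 432 relabellings. As a block in a fit of the day 14 fish alone, the letter gave 0 for any salinity and 0 for 8 against 28 ppt, as that fit did without the letter. Tank set and letter as a factor gave 2 for average time, 0 for time at 8 ppt and 34 for time at 20 ppt. That fit held only the fish of the 7 pairs, a single pair of them at 12 ppt. As a random effect, with all 19 fish in the model, they gave 25 for time at 8 ppt.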

Other observations

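The tests here on the 3 fish that stand apart, the 12 and 20 ppt fish, the 28 ppt fish b, the spread on each day and in each group, the read totals by day, the detected transcripts and the direction of the change at 28 ppt were chosen after the results they bear on had been seen. Those on other splits of the fish, on thinning for the change over time and on the wider set of genes between 12 and 20 ppt were chosen before. Of 3 hypothesis tests of one family, p-values adjusted over the 3 follow each raw value.

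More transcripts were detected in the fish at 8 ppt on day 14. With each library thinned to the same size factor, which left on average 4584894, 4932754, 6737953 and 6706288 reads at 8, 12, 20 and 28 ppt, 19308 ± 380 transcripts (SD, n = 3) had at least 1 read at 8 ppt, 17728 ± 1081 (SD, n = 2) at 12 ppt, 16372 ± 488 (SD, n = 3) at 20 ppt and 16390 ± 1682 (SD, n = 3) at 28 ppt. The day 0 tank sets had 17762 ± 1226, 17844 ± 1237 and 17142 ± 1352 (SD, n = 3, 2 and 3 for 8, 12 and 20 ppt). Detection differed among the 4 salinities by an exact permutation test over 92400 arrangements (p = 0.0314, adjusted p = 0.0471), but not without 8 ppt fish a, b or c (p = 0.0911, 0.113 and 0.0697), 20 ppt fish a, b or c (0.0570, 0.0552 and 0.0579) or 28 ppt fish c (0.0565). The 8 ppt mean was 2917 transcripts above the higher of the 20 and 28 ppt means; thinned to equal totals of 8255387 reads, which leaves the 8 ppt libraries more reads outside the 100 most abundant transcripts, the difference was 3015 (exact permutation p = 0.0326).

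Fish of 1 group differed more from each other on day 14 than on day 0 on average over all fish, but not at 8 ppt. The mean within-group variance per gene was 0.293 at 8 ppt on day 14, against 0.587, 0.637 and 0.660 at 12, 20 and 28 ppt and 0.366, 0.324 and 0.399 in the 8, 12 and 20 ppt tank sets of day 0, so that the lowest day 14 group was at 0.7345 of the highest day 0 group. Over all fish it was 0.541 ± 0.167 (SD over 11 fish) on day 14 and 0.368 ± 0.0476 (SD over 8 fish) on day 0 (exact permutation p = 0.015, adjusted p = 0.0450, 75582 arrangements), with p between 0.00206 and 0.0449 with each fish left out in turn. The 20 and 28 ppt groups hold the 3 fish that stand apart on the first component, and without these the exact permutation test gave p = 0.155 (7 day 14 fish left in groups of 2 or more). These permutation tests treat the fish as independent units. Deviations from a group mean are tied within a group, and equal in a group of 2, so the tests cannot settle a difference between the days. Day 14 libraries had on average 1.192 times the reads of day 0 libraries.

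The first pattern weighed is the position of 20 ppt fish c and 28 ppt fish a and c of day 14 on the first component, where their gap to the other 16 fish was 0.246 of the whole range. Reads argue against low depth: after thinning all libraries to the same size factor the gap was 1.317 times that before. The 100 most abundant transcripts took 50.6% to 53.9% of reads in these fish and 29.5% to 46.4% in the others, yet without them the gap was 0.978 of that with them under the size factor scaling the deposited values use; under scaling by library totals it went from 0.158 to 0.0371. A larger share of 1 tissue in the pool may place these fish there, and cannot be told apart from a state of the fish, since 0 marker lists could be matched to the identifiers. Salinity alone did not place them, because 28 ppt fish b lay among the others, at -24.4.

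The second pattern is the change from day 0 to day 14. Random splits argue against chance for the average of the lowered tanks, where the real split gave 527 genes and the highest of the others 2 (1 of 100 splits as large). The same holds for 28 ppt against day 0, with 102 genes against 16 (1 of 100). A share of 1 in 100 is the smallest these splits can give. The count of 102 was also 5 without 28 ppt fish a and 0 with only the compared groups in the model. Thinning did not lower the number of transcripts called: with libraries thinned to equal totals, limma voom called 458, 1.212 times the 378 before. Depth is not settled by this for the 527 genes, since the depth of the gene table is unknown. Limma voom also called 99 transcripts among the day 0 tank sets. Part of the change is consistent with time without a change in water: with the day 0 fish split, and 527 genes of smallest p (most of them not called) chosen in each split without the fish they were read in, at least 74.0% had the same sign at 28 ppt, where simulated unchanged genes gave at most 54.3%, though real genes vary together and these simulated genes do not. Growth, handling and any batch that follows the sampling day cannot be told apart here.

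The third pattern is the set of 8 genes between 8 and 28 ppt. The 12 and 20 ppt fish, which entered the choice of these genes through the variance but not the difference, differed in the same direction in 8 of 8, by a median of 1.03 on the log2 scale, and a graded response to salinity may be a hypothesis to follow up, but an exact permutation of the 5 fish gave p = 0.2 (adjusted p = 0.2; 0.1 is the smallest it can give), and of 8 genes chosen by smallest p from the 8 and 28 ppt fish alone 6 went that way, by a median of 0.136 (p = 0.4). It is not particular to the 8: of the other 2830 genes at unadjusted p under 0.05 between 8 and 28 ppt, 81.7% also went that way between 12 and 20 ppt, with a median 0.57 of that of the 8, so a drift of many genes along the salinities stays open. As 20 ppt fish c stands apart together with 28 ppt fish a and c, that share may rest on these fish, which was not tested. Measured against 28 ppt fish b alone, the difference was 0.7808 of that against all 3 fish (2.64 against 3.38, log2), which leaves open how much of it rests on fish a and c. The 10 splits of 6 fish are too few for a share under 0.05: the real split gave 8 genes, and the highest other, with 8 ppt fish a beside 28 ppt fish a and c, gave 3 (1 of 10 as large).

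The other comparisons of 3 with 3 fish also have 10 splits, too few for a share under 0.05. Time at 8 ppt gave 15 genes and at 20 ppt 32, with 0 in each of the others (1 of 10 as large in each). For 8 against 20 ppt the real split gave 0 genes and the highest other 2, and for 20 against 28 ppt 0 and 517; with a real count of 0, 10 of 10 are as large by construction, which tests nothing. The split with 517 genes set 20 ppt fish a and b and 28 ppt fish b against 20 ppt fish c and 28 ppt fish a and c, the 3 fish of the first pattern.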
